A study of Mus musculus with 16 samples.

How the data were processed

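Single-end reads of 75 bp were made from 16 libraries of sorted cells, 4 each of naive glia, infected glia, naive non-glia and infected non-glia from the small-intestinal tunica muscularis of Sox10CreERT2;Rosa26tdTomato mice. Per the labels, cDNA was amplified with a NuGEN Ovation kit, sheared to 200 bp, taken through 7 PCR cycles and sequenced on a HiSeq4000. The submitters' processing notes name STAR 2.5.2, RSEM 1.3.0, DESeq2 1.10.1 and genome build GRCm38. The annotation release, the strandedness of the libraries and any trimming or duplicate removal are not given in the sources used here. The deposited table holds RSEM expected counts, 1 column per library and 1 Ensembl gene ID per line, not normalized and with replicates not pooled. Expected counts were rounded to whole numbers before use. Reads that fit several genes are divided by RSEM among them, so genes of families with shared sequence, such as the guanylate-binding proteins and the H2-Q genes, are less certain. All 51912 gene IDs were looked up in the GENCODE M21 annotation of GRCm38 and its symbol table. A symbol was paired with 51633 of them, and 279 stayed without one.

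Total counts per library ran from 6036798 to 18953928, which is the depth behind every value. Part of it, 21.5 to 56.4% per library, lay on mitochondrial rRNA and the gene model CT010467.1. TMM factors ran from 0.419 to 1.39. The biological coefficient of variation was 63.6% for infection in glia, 82.2% for infection in non-glia, 59.7% and 83.9% for the fractions in naive and infected mice and 77.6% for the difference in response. The reads are PCR products without molecular identifiers, and the floor used for genes with 0 counts covers counting error only. SDs and standard errors also cover the spread between libraries. A gene with 0 counts in a group was set against a floor of 3 counts over that group's summed effective library size.

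There were 5 comparisons: infected against naive glia, infected against naive non-glia, glia against non-glia in naive and in infected mice, each within its 8 libraries, and the difference between the infection responses over all 16. Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided, after filterByExpr (minimum count 10, minimum total 15) and TMM scaling, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM are TMM-scaled, and means are given with the SD over 4 libraries. Log2 fold changes are edgeR's, with a standard error from the same fit. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for lists with at least 3 tested members, adjusted over the lists of a comparison. The same test with the correlation estimated per list is given beside it, since the preset one understates how far the genes of a cell type move together. The rotation test fry of limma, adjusted over the lists, is given for the difference in response of leukocyte lists only. A list count "adjusted over the list alone" uses only the p-values of that list's members.

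The 31 lists covered the interferon-gamma response, type I interferon-stimulated genes, MHC class I and peptide loading, MHC class II, interferon receptors and JAKs, the IL-4 and IL-13 type 2 response, cytokines and chemokines, neurotrophic factors and reactive glia. They also covered markers of enteric glia, enteric neurons, smooth muscle, interstitial cells of Cajal, fibroblasts and PDGFRA cells, mesothelium, endothelium, macrophages, monocytes, T and NK cells, B and plasma cells, neutrophils, eosinophils, mast cells, epithelium and erythroid cells. The rest were cell cycle, immediate early and dissociation stress, extracellular matrix and wound repair, cholesterol synthesis, mitochondrially encoded and sex-linked genes. Some genes belong to several lists: the type 2 list shares Chil3 with the monocyte list and Mrc1 with the macrophage list, and the MHC class I list shares immunoproteasome genes with the interferon-gamma list. Named genes were chosen by rule. Sox10, S100b, Gfap, Cxcl10, Ifngr1 and Ifngr2 were followed in every comparison. Some genes that the rule names are not reported here. From each comparison came the 10 higher and 10 lower genes of largest fold change among those called, with a mean log2 CPM of at least 1 and groups that did not overlap (a condition dropped for the difference in response), leaving out predicted gene models and immunoglobulin and T cell receptor segments. From each list came up to 4 members of smallest p; fewer were named where one would repeat another. The comparisons, tests, lists and naming rule and most other settings tried were chosen before the data were examined.

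The other settings tried were DESeq2 size factors, no filter and a stricter filter (CPM of at least 1 in 4 libraries), the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, all 16 libraries in the fit, the replicate number as a block, a test against a log2 fold change of 1, a prior count of 0.5 for the lists, and each library left out in turn. A term for library class, the low-class libraries alone, and these without infected glia 3 were chosen after seeing the data. The class is the share of counts on mt-Rnr1, above or below 6%; nothing in the labels explains it. Whether the replicate numbers pair libraries of the same mouse was checked by correlating the deviations of libraries from their group means. In naive mice the same-number pairs of glia and non-glia correlated at 0.198, 0.205, 0.196 and 0.249, each above every other pairing in its own set of 4. In infected mice they correlated at 0.306, 0.157 and -0.0816, and number 3 differed in sex, so those numbers do not pair mice throughout. Naive and infected glia, from different mice, correlated by number at 0.147, 0.129 and 0.197, each the highest for its naive library. Naive and infected non-glia did so at 0.188, 0.172, -0.121 and 0.193, and naive non-glia 1 and 2 correlated more with other numbers (0.220 and 0.272). Shared library class can raise these values. Among low-class libraries they were 0.0159, 0.168 and 0.142 in glia, -0.165 and -0.134 in non-glia and 0.183, 0.188 and 0.0931 between the fractions of naive mice. The tests are therefore unpaired, with the block as an alternative. Glia and non-glia came from the same animals at least in part, so the overlap of their infection responses is not one of independent animals, and each naive group serves both an infection and a fraction comparison.

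The chain was tested on simulated data, negative binomial counts with the means, depths and dispersions of these libraries, in which 50 genes each were changed 2-, 4-, 8- and 16-fold. It recovered 0, 18, 50 and 82% of them in the glial infection comparison, 0, 4, 38 and 42% in non-glia, 0, 26, 60 and 74% for the fractions in naive mice, 0, 2, 26 and 48% in infected mice, and 0, 0, 10 and 20% for the difference in response. False calls made up 2.60, 2.33, 1.22, 2.56 and 0% of its calls in the 5 comparisons. In the simulated data changes of 2-fold were thus out of reach for single genes. A gene that did not pass in the real data may have changed by that much. The simulated fraction comparisons held 82 and 39 calls, against 3235 and 2146 in the real ones. With more calls the adjusted threshold is less strict, so the recovery rates do not carry over to those comparisons. Genes varied independently in the simulated data, without library classes or pairs of libraries, and each rate came from a single draw.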

Results

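RNA was sequenced from cells of the tunica muscularis, the muscle layer of the small intestine, of Sox10CreERT2;Rosa26tdTomato mice. In these mice tamoxifen switches on the red fluorescent protein tdTomato in cells that express Sox10, which in the gut wall are the enteric glia, the support cells of the gut's own nerve net. Tamoxifen was given 10 days before isolation, and the infected mice had carried the roundworm Heligmosomoides polygyrus for 7 days. Fluorescence-activated sorting parted tdTomato-positive cells, called glia here, from tdTomato-negative cells, called non-glia, a mixture of everything else in the layer. Each fraction gave 4 libraries from naive and 4 from infected mice, 16 in all.

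Naive glia 1, 2, 3 and 4 held 12149965, 10900352, 7239813 and 12067157 counts. Infected glia 1, 2, 3 and 5 held 12452997, 11367367, 6036798 and 13169340. Naive non-glia 1, 2, 3 and 4 held 9697404, 10966420, 10652612 and 17013240, and infected non-glia 1, 2, 3 and 4 held 11132271, 11485126, 15197743 and 18953928. Mitochondrial rRNA and the gene model CT010467.1 together took 21.5 to 56.4% of the counts, and 10040 to 16066 genes per library had at least 10 counts. In 5 libraries the mitochondrial 12S rRNA gene mt-Rnr1 took 8.75 to 14.9% of the counts, against 2.07 to 4.71% in the other 11. These 5, called the high class here, were naive glia 4, infected glia 5, naive non-glia 4 and infected non-glia 3 and 4. They held 10040 to 12699 genes with at least 10 counts, against 13917 to 16066 in the low class.

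**Figure D1:**
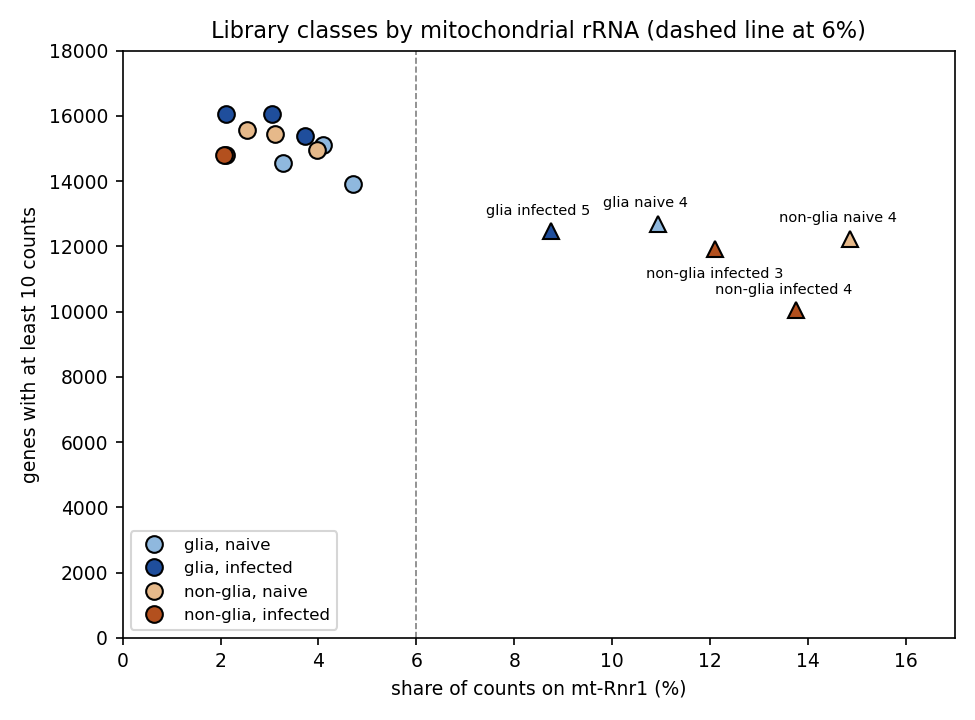
Each point is 1 library, with the share of its counts on mt-Rnr1 (%) on the x axis and the number of genes with at least 10 counts on the y axis, coloured by group. Triangles right of the dashed line at 6% are the 5 high-class libraries, at 10040 to 12699 genes, and circles are the other 11, at 13917 to 16066.

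How enteric glia respond to the worm was the question of the study's design, and the comparison of infected with naive glia addresses it. The infected glial sort held more RNA of the interferon-gamma response, of both classes of antigen presentation and of cytokines and chemokines. It also held more RNA of the alternative activation program that the type 2 cytokines IL-4 and IL-13 drive, and of macrophages, monocytes and lymphocytes. Proliferation genes ranked higher too, but not with an estimated correlation (0.0543). No marker gene of the glia themselves passed the threshold in either direction. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 172 of 15028 genes rose and 0 fell. At an unadjusted p under 0.05, 929 genes lay higher and 311 lower, and DESeq2 and limma-voom called 29 and 113 lower genes. All 172 genes that rose did so without overlap between the groups. Over all genes tested the groups were apart for 1202 (8.0%), where chance gives 2.86%. The count rested on single libraries. It was 96 without naive glia 1, 15 without naive glia 2, 52 without naive glia 3 and 77 without infected glia 3. Within the low-class libraries alone, 3 naive and 3 infected, 312 genes passed, of which 163 were among the 172.

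Interferon-gamma switches on guanylate-binding proteins and immunity-related GTPases, which attack pathogens inside the cell. Of the 34 measured genes of this response, 21 rose and 0 fell in infected glia, with 27 higher when adjusted over the list alone. The median log2 fold change was 2.12, and 1.97 among low-class libraries (camera adjusted p = 3.54e-35; 0.0122 with an estimated correlation). The GTPase genes Gbp4 and Gbp10 rose by 5.43 (SE 0.39, edgeR adjusted p = 1.31e-04) and 5.35 (SE 0.39, adjusted p = 1.31e-04) on the log2 scale. Guanylate-binding paralogs share sequence, so the division of reads among them is uncertain. Gbp4 went from 1.83 ± 0.635 to 78.2 ± 23.4 CPM (scaled counts, mean ± SD, n = 4 per group). Iigp1, an immunity-related GTPase, went from 23.2 ± 7.96 to 217 ± 65.2 CPM (adjusted p = 0.00240). Cxcl10, a chemokine for activated T cells, went from 57.3 ± 33.0 to 250.2 ± 65.6 CPM (log2 2.15, adjusted p = 0.0301). Its adjusted p was 0.109 without naive glia 1, 0.0569 without naive glia 2, 0.131 without naive glia 3, 0.0529 without infected glia 1, 0.0936 without infected glia 2 and 0.0832 without infected glia 3. The receptor genes Ifngr1 (log2 0.03, adjusted p = 0.991) and Ifngr2 (log2 0.63, adjusted p = 0.770) did not pass, and 0 of the 8 interferon receptor and JAK genes rose (list adjusted p = 0.547).

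Of the 32 genes that answer chiefly to type I interferon 3 passed, or 13 when adjusted over the list alone, with a median of 1.06 (1.04 among low-class libraries; camera adjusted p = 1.07e-13, 0.0185 with an estimated correlation). The nucleic acid sensor Zbp1 rose by 2.72 (edgeR adjusted p = 0.0161); its adjusted p was 0.0589 without naive glia 1, 0.0868 without naive glia 2, 0.0708 without naive glia 3 and 0.0578 without infected glia 3. Of the 20 genes of MHC class I and peptide loading, 7 rose, or 13 when adjusted over the list alone, with a median of 1.22 (1.03 among low-class libraries; adjusted p = 4.56e-15, 0.0185 with an estimated correlation). Among them the immunoproteasome subunit gene Psmb9, which shapes the peptides that class I molecules present, rose by 2.24 (adjusted p = 0.0112; 0.0605 without naive glia 2 and 0.0592 without naive glia 3). MHC class II, which presents peptides to helper T cells and is found on professional antigen-presenting cells, had 5 of 7 genes higher, and 7 when adjusted over the list alone. Its median was 3.01 (2.94 among low-class libraries; adjusted p = 2.49e-14, 0.0295 with an estimated correlation). The invariant chain gene Cd74 went from 66.9 ± 25.2 to 545 ± 161 CPM (log2 3.05, adjusted p = 0.00327), and the peptide-loading chaperone gene H2-DMa rose by 3.32 (adjusted p = 0.00327).

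**Figure D2:**
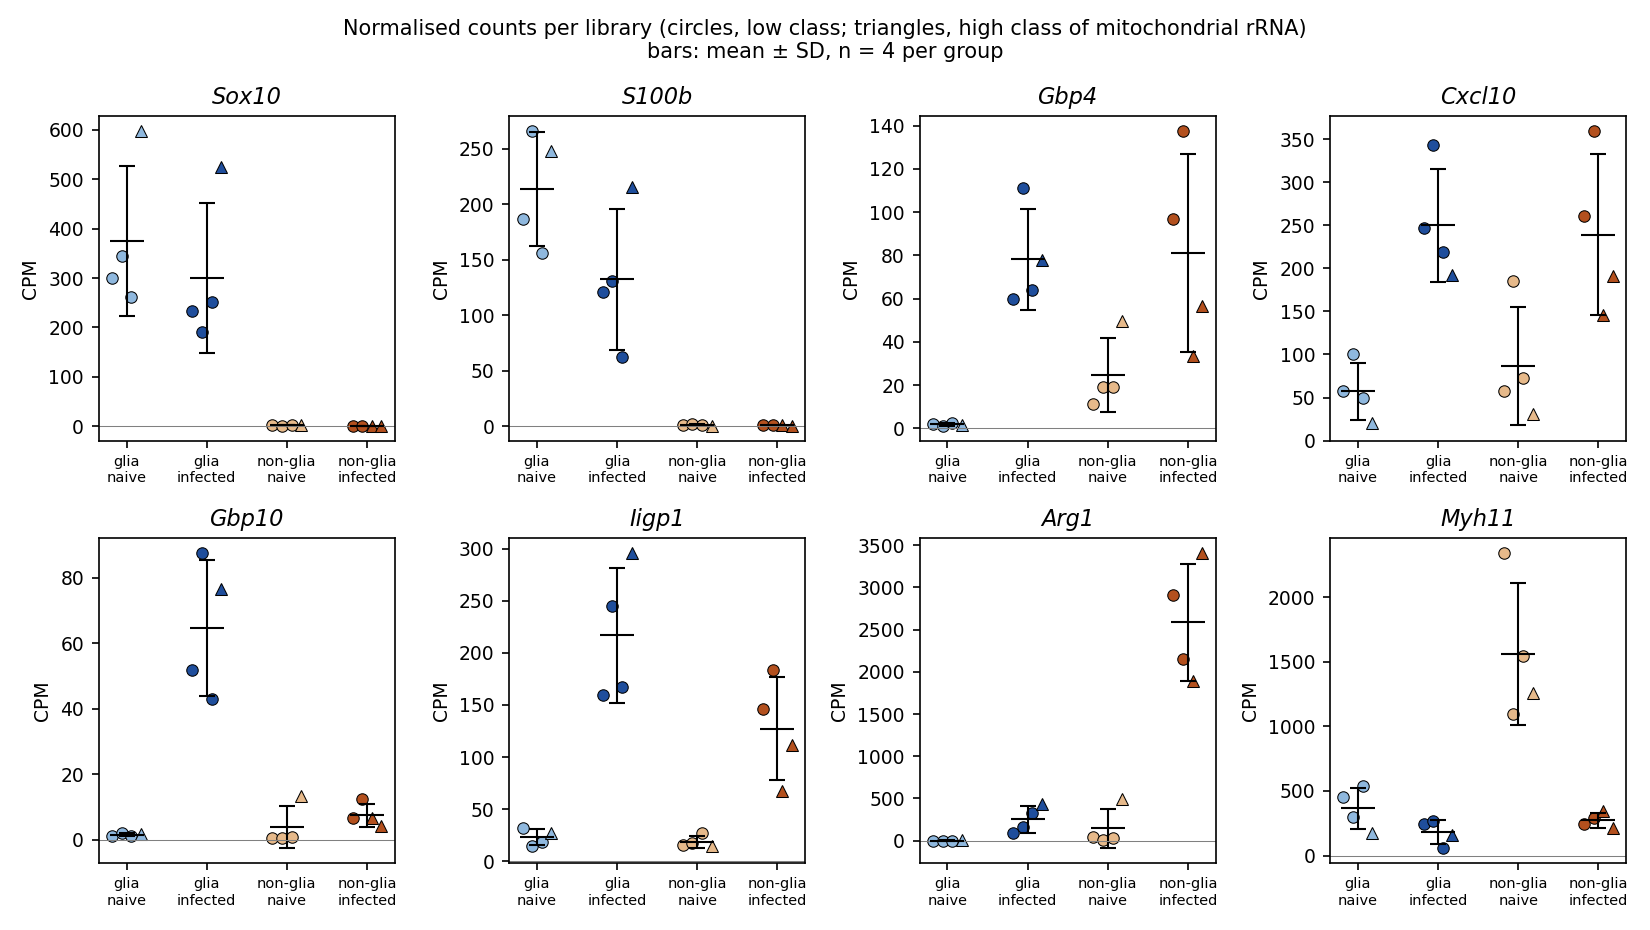
CPM in each library for 8 genes, in the 4 groups of 4 libraries, with circles for low-class and triangles for high-class libraries and bars for the mean ± SD. Iigp1 averaged 23.2 CPM in naive and 217 CPM in infected glia, while Sox10 averaged 375 and 300.0 CPM.

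IL-4 and IL-13, the cytokines of the immune response to worms, drive macrophages and other cells into a wound-repair state. Of 15 measured genes of this response, 8 rose in infected glia, and 10 when adjusted over the list alone, with a median of 3.47 (3.53 among low-class libraries; camera adjusted p = 2.23e-18, 0.0122 with an estimated correlation). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), the arginase of alternatively activated macrophages, went from 2.06 ± 0.987 to 252 ± 156 CPM (log2 6.96, SE 0.61, edgeR adjusted p = 6.95e-04). Chil3, a chitinase-like protein gene of the same state, went from 3 counts in all 4 naive libraries together to 2337 in the infected ones (adjusted p = 9.36e-04). Of 30 cytokine and chemokine genes 10 rose, or 15 when adjusted over the list alone, with a median of 2.11 (1.31 among low-class libraries; adjusted p = 1.13e-16, 0.0185 with an estimated correlation). Ccl8 rose by 6.51 (adjusted p = 0.00300) and Ccl6 by 5.17 (adjusted p = 0.00309). Ccl2, the main attractant of monocytes, went from 25.9 ± 9.06 to 130 ± 35.4 CPM (log2 2.35, adjusted p = 0.00796; 0.0569 without naive glia 2). Genes of glial reactivity, the state of injured astrocytes, had 3 of 16 higher and a median of 0.45 (adjusted p = 1.83e-04, but 0.0713 with an estimated correlation). Lcn2, an iron-binding acute-phase protein gene, rose by 6.10 (adjusted p = 0.00308), while Gfap did not pass. Of 28 cell cycle genes 4 rose, or 13 when adjusted over the list alone, with a median of 2.42 (adjusted p = 1.53e-19, 0.0543 with an estimated correlation). The proliferation marker Mki67 rose by 3.75 (adjusted p = 0.00844; 0.0569 without naive glia 2). Extracellular matrix and wound repair genes had 2 of 21 higher, or 6 when adjusted over the list alone, and a median of 0.57 (adjusted p = 7.22e-07, 0.0645 with an estimated correlation). Among them Tgfbi, an adhesion protein gene that TGF-beta induces, rose by 3.12 (adjusted p = 0.00796; 0.0569 without naive glia 2).

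Markers of leukocytes, which the sort was meant to leave out of the glial fraction, rose in it as well. Of 10 measured T and NK cell markers 7 rose, with 9 when adjusted over the list alone and a median of 6.49 (5.16 among low-class libraries; camera adjusted p = 3.30e-16, 0.0411 with an estimated correlation). Gzmb, a protease that cytotoxic lymphocytes use to kill, had 7 counts over the naive and 1965 over the infected libraries (log2 8.23, edgeR adjusted p = 0.00265). Macrophage markers had 8 of 13 higher, or 10 when adjusted over the list alone, with a median of 2.41 (2.22 among low-class libraries; adjusted p = 3.30e-16, 0.0122 with an estimated correlation). C1qc, which encodes a complement subunit made by tissue macrophages, rose by 3.04 (adjusted p = 0.00799; 0.0569 without naive glia 2). Monocyte markers had 5 of 8 higher, or 7 when adjusted over the list alone, with a median of 2.63 (2.48 among low-class libraries; adjusted p = 1.07e-13, 0.0185 with an estimated correlation). Ly6c2, the surface marker of inflammatory monocytes, had 0 counts in naive glia and was at least 97.7-fold higher in infected glia, against a floor of 3 counts over the group (adjusted p = 0.0159; 0.0719 without naive glia 2, 0.0528 without naive glia 3 and 0.0591 without infected glia 3). Slfn4, an interferon-induced gene of myeloid cells, was at least 193-fold higher on the same floor (adjusted p = 0.0173; 0.0733 without naive glia 2, 0.0566 without naive glia 3 and 0.0581 without infected glia 3).

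No lineage gene of enteric glia passed the threshold on infection, although most estimates were negative. Sox10 (ENSMUSG00000033006, chromosome 15, 79154908 to 79165240, GRCm38), the transcription factor that specifies glia, went from 375 ± 152 to 300.0 ± 152 CPM and did not pass (edgeR log2 -0.31, adjusted p = 0.891). The calcium-binding protein gene S100b (log2 -0.68, adjusted p = 0.672) and the filament gene Gfap (-0.35, 0.890) did not pass either. Of 21 enteric glia markers 0 were called higher and 0 lower. The log2 estimate was above 0 for 2 of the 21, with a median of -0.50 (-0.50 among low-class libraries). As a list they ranked lower than other genes by camera's preset correlation (adjusted p = 1.83e-04), but not with an estimated correlation (0.0645). Smooth muscle markers ranked lower too (median -0.69, adjusted p = 1.83e-04, 0.371 with an estimated correlation), as did immediate early and dissociation stress genes (-0.51, 0.0261, 0.417), with 0 and 0 members called. Enteric neuron markers ranked higher (0.61, 0.0354, 0.417 with an estimated correlation), with 0 of 19 called. The neuron list had an adjusted p of 0.0649 without naive glia 2, 0.0784 without naive glia 4 and 0.395 without infected glia 1, and the immediate early list one of 0.132 without naive glia 2, 0.0682 without naive glia 3, 0.119 without infected glia 2 and 0.0595 without infected glia 3. Lists of fibroblasts (adjusted p = 0.233), interstitial cells of Cajal (0.385), mesothelium (0.754), endothelium (0.547) and epithelium (0.533) did not pass. Neither did cholesterol synthesis (0.376), mitochondrially encoded genes (0.999), neurotrophic factors (0.766) or sex-linked genes (0.319). With 1 library left out, mesothelial (0.0177 without naive glia 4), epithelial (0.0384 without naive glia 4) and cholesterol genes (0.0181 without infected glia 3) did. B and plasma cell, eosinophil, erythroid, neutrophil and mast cell lists had fewer than 3 tested members. The sex-linked list pools Xist with Y-linked genes, which differ between the sexes in opposite directions, so its test says little about sex in any comparison. Sex was not balanced in glia. Naive glia 1 held no Y-linked RNA and naive glia 3 held Xist at 198 CPM, while every infected glial library held Y-linked RNA and Xist at no more than 4.42 CPM. No term for sex was fitted.

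**Figure D3:**
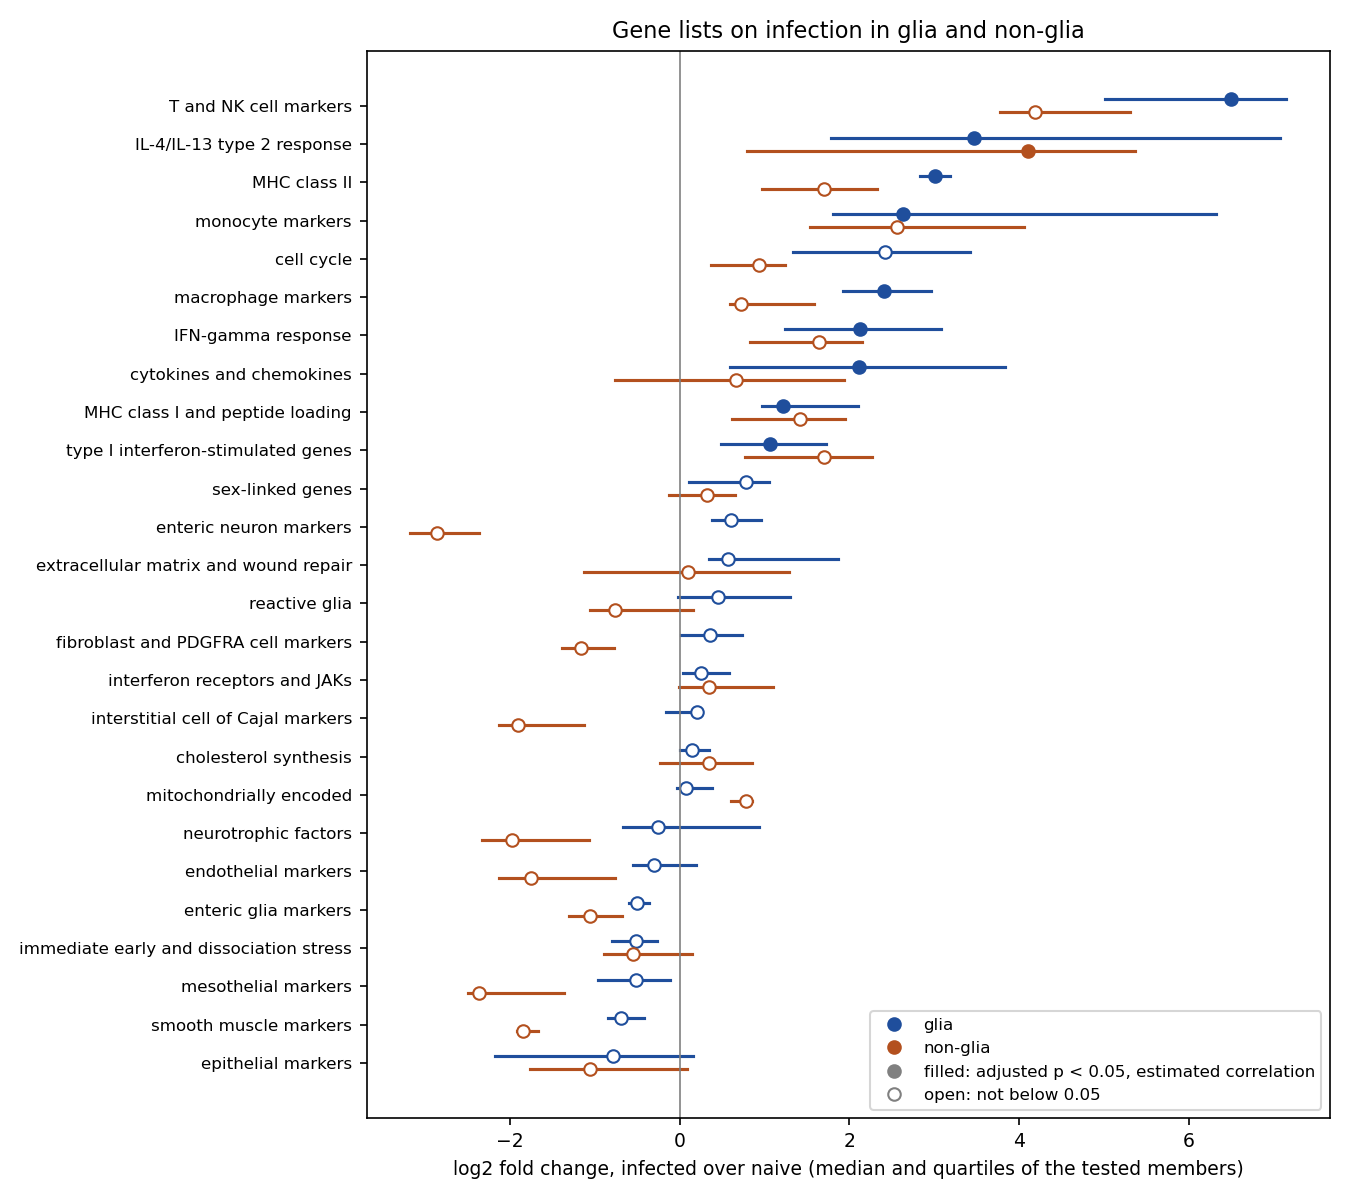
Median log2 fold change on infection (x axis, infected over naive) of the tested members of each gene list (y axis) in glia and non-glia, with bars from the lower to the upper quartile. Filled points have an adjusted p under 0.05 with an estimated correlation, as the IFN-gamma list does in glia (median 2.12) and not in non-glia (median 1.65).

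The same comparison in non-glia asks how the rest of the muscle layer changed with infection. Lists of the type I interferon, interferon-gamma and type 2 responses and of T and NK cells ranked higher and smooth muscle markers lower by camera's preset correlation, each with part of its members called. With an estimated correlation the type 2 list alone kept its call, while the adjusted p was 0.209 for type I, 0.0576 for interferon-gamma, 0.0781 for T and NK cells and 0.172 for smooth muscle. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 176 of 14481 genes rose and 58 fell, 114 genes in all with the replicate number as a block. The balance turned with method and libraries, at 99 higher and 15 lower with the block, 528 higher and 608 lower by DESeq2, 3305 and 4028 by limma-voom and 2668 and 3554 among low-class libraries. Every called gene had groups that did not overlap. Over all genes tested the groups were apart for 2819 (19.5%), where chance gives 2.86%. The count of 234 moved with nearly every library left out. It was 6, 8 and 17 without naive non-glia 1, 2 and 3, and 406 without naive non-glia 4. Without infected non-glia 1, 2 and 3 it was 78, 32 and 87. The low-class libraries alone, 3 naive and 2 infected, gave 6222 genes, which included all 234, and a term for library class gave 503.

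Of 34 interferon-gamma response genes in non-glia 12 rose, or 22 when adjusted over the list alone, with a median log2 fold change of 1.65 (1.86 among low-class libraries; camera adjusted p = 4.44e-15, but 0.0576 with an estimated correlation). Cxcl10 did not pass (n = 4 each; log2 1.45, edgeR adjusted p = 0.200). Ifngr1 (log2 0.58, adjusted p = 0.444) and Ifngr2 (1.21, 0.162) did not pass, nor did the receptor and JAK list (adjusted p = 0.253). Of 32 type I interferon-stimulated genes 6 rose, or 18 when adjusted over the list alone, with a median of 1.70 (1.86 among low-class and 0.49 among high-class libraries; adjusted p = 1.71e-10, 0.209 with an estimated correlation). The list's mean log2 CPM was 5.64, 6.21, 3.85 and 5.87 in infected non-glia 1, 2, 3 and 4, and 3.63 to 4.28 in naive non-glia. Infected non-glia 3 thus lay within the naive range, while infected non-glia 4, also of the high class, lay above it. Oas3, which makes the signal for antiviral RNA decay, rose from 7.62 ± 2.25 to 162 ± 70.6 CPM (log2 4.41, adjusted p = 0.00418). MHC class I genes had 5 of 20 higher (median 1.41, adjusted p = 8.11e-08, 0.0576 with an estimated correlation) and MHC class II 1 of 10 (1.70, 1.45e-05, 0.192), or 11 and 5 when adjusted over the list alone.

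The type 2 response was the 1 list called in non-glia with an estimated correlation (adjusted p = 0.0112; 4.32e-12 with the preset one). Of its 19 genes 8 rose, or 13 when adjusted over the list alone, with a median of 4.11 (2.98 among low-class libraries). Pdcd1lg2, which encodes the inhibitory ligand PD-L2 and is induced by IL-4, rose from 0.102 ± 0.145 to 109 ± 34.8 CPM (edgeR adjusted p = 0.00257), and Ccl8, an attractant of type 2 helper T cells, by 7.01 on the log2 scale (0.00819). The ribonuclease gene Rnase2a rose by 8.08 (0.00434). The homeobox gene Msx3 had 2 counts over the naive and 1085 over the infected libraries (0.00418). Il13 itself rose from 0.137 ± 0.225 to 18.7 ± 16.6 CPM (adjusted p = 0.0371), a call that ended with the replicate block and without each of 6 libraries, at 0.124 without naive non-glia 1, 0.0696 without naive non-glia 2, 0.131 without naive non-glia 3, 0.0568 without infected non-glia 1, 0.0627 without infected non-glia 2 and 0.0813 without infected non-glia 3. T and NK cell markers had 9 of 16 higher, or 15 when adjusted over the list alone, with a median of 4.18 (adjusted p = 3.69e-19, 0.0781 with an estimated correlation). Nkg7, a cytotoxic granule gene, rose by 5.36 (0.0163; 0.0716 without naive non-glia 1 and 0.0696 without naive non-glia 2). Macrophage markers had 2 of 13 higher (median 0.72, and 1.18 among low-class libraries; adjusted p = 2.25e-04, 0.195 with an estimated correlation) and monocyte markers 2 of 8 (2.56, 2.22e-06, 0.172). Cytokines and chemokines had 3 of 32 higher (0.67, and 1.11 among low-class libraries; 9.42e-04, 0.172). Neutrophil markers had 1 of 7 higher (1.35, with 3.95 among low-class and 0.11 among high-class libraries; 7.91e-04, 0.192). Eosinophil markers (0 of 4 called, median 2.94, 0.00196, 0.192), B and plasma cell markers (0 of 4, 2.36, 0.0250, 0.313), cell cycle genes (0 of 28, 0.94, 3.50e-04, 0.284) and cholesterol synthesis (0 of 20, 0.35, 0.0342, 0.516) ranked higher by the preset correlation alone. The median of B and plasma cell markers was 0.34 among low-class (adjusted p = 0.536) and 4.51 among high-class libraries, so the call rested on the high class; a term for library class ended it (0.127). Their adjusted p was 0.0645 without naive non-glia 2, 0.0993 without infected non-glia 3 and 0.0961 without infected non-glia 4, and cholesterol synthesis one of 0.0871 without naive non-glia 1, 0.125 without naive non-glia 4 and 0.0869 without infected non-glia 1.

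Non-glia is a mixture, and CPM are relative to all of its RNA. A changed mix of cells therefore cannot be told apart from changed expression within cells for any list here. Smooth muscle markers, the contractile proteins of the layer, fell in 4 of 12 cases in non-glia, or 12 when adjusted over the list alone. Their median was -1.84 (-1.94 among low-class libraries; camera adjusted p = 6.17e-08, 0.172 with an estimated correlation). The smooth muscle myosin gene Myh11 went from 1560 ± 553 to 273 ± 56.9 CPM (log2 -2.50, SE 0.40, edgeR adjusted p = 0.0200; 0.0716 without naive non-glia 1, 0.0696 without naive non-glia 2, 0.0763 without naive non-glia 3, 0.0568 without infected non-glia 1 and 0.0643 without infected non-glia 2). Pgm5, an adhesion protein gene of contractile cells, fell by 2.61 on the log2 scale (adjusted p = 0.0239; 0.0927 without naive non-glia 1, 0.0815 without naive non-glia 2, 0.0914 without naive non-glia 3, 0.0561 without infected non-glia 1, 0.0626 without infected non-glia 2 and 0.0548 without infected non-glia 3). Aqp1, the water channel gene of small vessels and mesothelium, went from 103 ± 45.4 to 16.2 ± 10.4 CPM (adjusted p = 0.0360). It lost the call with the replicate block and in the fits without 1 library (0.0779 without naive non-glia 1, 0.102 without naive non-glia 2, 0.123 without naive non-glia 3, 0.105 without infected non-glia 2 and 0.0828 without infected non-glia 3). Lists of the other resident cells ranked lower with the preset correlation and not with an estimated one. Enteric neurons had a median of -2.85 (adjusted p = 4.75e-05, 0.317 with an estimated correlation), mesothelium -2.37 (the same 2 values being 0.00299 and 0.284), fibroblasts -1.16 (0.00120, 0.284) and endothelium -1.75 (0.00567, 0.313), with 0 members called in each. Interstitial cells of Cajal (1 of 5 lower, median -1.91, 0.0275, 0.370), enteric glia markers (0 of 16, -1.05, 0.0199, 0.430) and neurotrophic factors (0 of 12, -1.98, 0.0345, 0.368) did the same. These calls ended for endothelium (0.165 without naive non-glia 4), mesothelium (0.0515 with all 16 libraries in the fit), glia markers (0.0585 without infected non-glia 3) and neurotrophic factors (0.0700 without naive non-glia 4). They ended as well for interstitial cells (0.125 without naive non-glia 4, 0.0534 without infected non-glia 2, 0.158 among low-class libraries and 0.0653 with the replicate block). Epithelial (adjusted p = 0.367), erythroid (0.342), matrix (0.664), immediate early (0.327), mitochondrially encoded (0.0521), reactive glia (0.695) and sex-linked lists (0.626) did not pass, although erythroid (0.0336 without naive non-glia 3) and mitochondrially encoded genes (3.15e-04 without naive non-glia 4, 0.00132 without infected non-glia 1 and 0.00456 without infected non-glia 2) did with 1 library left out. Epithelial markers passed among low-class libraries (6.28e-04; median -2.39, against 0.86 among high-class ones), erythroid ones with a term for library class (0.0370) and mitochondrially encoded genes with the replicate block (0.00275). Mast cell markers had fewer than 3 tested members. Sox10 (log2 fold change -1.48, adjusted p = 0.429), S100b (-0.40, 0.864) and Gfap (-0.77, 0.781), present at trace levels in non-glia, did not pass on infection.

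Whether glia and non-glia responded alike was tested by overlap and by the difference in response itself. The chemokine gene Ccl8, an attractant of type 2 helper T cells, was among the immune genes that rose in both. The difference test picked out 1 gene, of fatty acid handling. Of 13371 genes tested in both fractions, 56 rose in both, of 170 and 154 that rose in each, where 1.96 would do so by chance (Fisher's exact test, p = 5.54e-69). That test treats genes as independent, which they are not. Among the 56 were lymphocyte genes such as Nkg7, Gzmb and Cd8a. RNA of non-glial cells in the glial sort, which stays open below, could bring such an overlap, so it does not show a response of the glia themselves. Of the 170 called in glia, 167 had a positive estimate in non-glia, and 147 of the 154 had one in glia. Across genes, which are not independent replicates, the fold changes of the fractions had a Pearson correlation of 0.363 and a Spearman correlation of 0.296. The interaction over all 16 libraries called 1 gene of 16770 by edgeR, at 1625 with an unadjusted p under 0.05, and 0 with the replicate block. That gene was Fabp5 (ENSMUSG00000027533, chromosome 3, 10012548 to 10016607), a fatty acid chaperone gene, at 82.6 ± 9.43 to 134 ± 13.0 CPM in glia and 14.2 ± 6.82 to 287 ± 39.4 CPM in non-glia (difference -3.64, SE 0.46, adjusted p = 0.00298). DESeq2 called 148 and limma-voom 3008 genes, and 6 passed by edgeR without naive non-glia 4. Cxcl10 did not differ in response by this test (difference 0.66, adjusted p = 0.778), and the interferon-gamma list did not either (median difference 0.42, adjusted p = 0.598). With camera's preset correlation, the response of 11 lists differed. Neurons had a median difference of 3.12 (adjusted p = 4.12e-07), macrophages 1.59 (0.00242) and cell cycle genes 1.69 (0.00363), glia minus non-glia; with an estimated correlation none differed (lowest adjusted p = 0.527). Over all 16770 genes the median difference was 0.32, so list medians are to be read against that value and not against 0. The median was positive and the test ranked the list lower for the type 2, MHC class I, T and NK cell, monocyte, neutrophil, epithelial and sex-linked lists, none of which passed. The medians of MHC class I (0.09) and sex-linked genes (0.08) lay below that of all genes. Why the others ranked lower was not tested.

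The comparison of glia with non-glia in naive mice asks what sets the sorted cells apart. By camera's preset correlation the glial sort was rich in genes of glial identity and of cholesterol synthesis. It was poor in markers of muscle, connective tissue, vessels, epithelium and leukocytes, while neuron markers did not differ as a list. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 1476 of 14778 genes were higher in glia and 1759 lower. Groups were apart for 4761 genes (32.2%), where chance gives 2.86%, and 5119 genes were called without naive non-glia 4. All 21 of 21 enteric glia markers were higher, with a median log2 difference of 7.34 (camera adjusted p = 2.32e-23, 0.0820 with an estimated correlation; no list passed with one in this comparison). Sox10 stood at 375 ± 152 against 1.81 ± 0.542 CPM (n = 4 each; log2 7.71, SE 0.45, adjusted p = 1.38e-05). With the log2 difference and adjusted p in parentheses, S100b (7.34, 1.43e-05) and Gfap (7.78, 5.81e-05) were higher in glia. Among the genes furthest above non-glia were Ajap1, an adherens junction gene (8.85, 4.69e-05), Gfra3, the artemin co-receptor gene (8.55, 1.91e-05), Sostdc1, a BMP and WNT antagonist gene (8.64, 4.66e-05), and Nrn1, a gene for neurite growth (8.49, 6.46e-05). The vomeronasal receptor gene Vmn1r181 was at least 108-fold higher in glia, against a floor of 3 counts over the non-glia (adjusted p = 0.00418). Naive glia 4 alone held it at 16.03 CPM, against 3.96 in the next library, which raised that bound. The neurotrophic and reactive glia lists had negative medians although the test ranked them higher, without passing. The neurotrophic list had members on both sides (3 higher and 4 lower of 13, adjusted p = 0.802), but Cntf, which keeps motor neurons alive, was higher by 6.67 (1.09e-04). Of 20 cholesterol synthesis genes 7 were higher and 0 lower (median 1.18, adjusted p = 6.76e-05, 0.354 with an estimated correlation).

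Macrophage markers were lower in naive glia for 12 of 13 genes (median -4.94, camera adjusted p = 5.37e-13; the lists that follow have their median and adjusted p in this order), MHC class II for 8 of 9 (-4.68, 3.10e-08), type 2 genes for 11 of 13 (-4.60, 2.27e-07) and cytokines for 21 of 28 (-3.51, 6.16e-10). Mesothelial markers were lower for 8 of 8 (-4.15, 1.90e-04), fibroblast markers for 10 of 11 (-2.31, 1.61e-08), endothelial markers for 10 of 12 (-3.55, 2.59e-07), smooth muscle markers for 11 of 12 (-1.50, 2.85e-06) and epithelial markers for 8 of 12 (-3.58, 1.36e-05). Kit, the receptor of interstitial cells of Cajal, was lower in glia by a log2 difference of -4.03 (edgeR adjusted p = 1.38e-05), and 4 of 5 markers of these cells were lower (-3.43, 6.56e-05). T and NK cell (5 of 8), monocyte (4 of 6), erythroid (4 of 5) and cell cycle markers (10 of 27) were lower as well, with list adjusted p of 2.89e-05, 0.00397, 5.28e-04 and 2.27e-07. Interferon-gamma response genes were 2 higher and 11 lower of 34 (-0.91, 0.00180), MHC class I 1 higher and 6 lower of 20 (-0.64, 0.0125), and matrix genes 3 higher and 11 lower of 21 (-0.91, 0.0113). Ifngr2 was lower in glia (log2 -1.17, adjusted p = 0.0287; 0.0902 without naive glia 1, 0.0796 without naive glia 2, 0.0898 without naive glia 3 and 0.0691 without naive non-glia 2); Ifngr1 (-0.02, 0.979) and Cxcl10 (-0.57, 0.534) did not pass. Clec4d, a myeloid lectin gene, was among the genes furthest below non-glia, with 3 counts in glia against 1844, and its log2 difference of -9.21 shrank to -4.82 without naive non-glia 4. Hdc, the histamine-making enzyme gene, lay lower by a log2 difference of -7.31 (0.00129). Neurons (1 of 19 higher, adjusted p = 0.754), type I interferon genes (6 higher and 5 lower of 32, 0.545), interferon receptors (0.472), reactive glia (0.802), immediate early (0.213), mitochondrially encoded (0.408) and sex-linked lists (0.802) did not pass. Immediate early (0.0168 without naive glia 4) and mitochondrially encoded genes (0.00843 without naive non-glia 4) did with 1 library left out, and both did among low-class libraries (0.0122 and 0.0188). B and plasma cell, neutrophil, eosinophil and mast cell lists had fewer than 3 tested members.

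The same comparison in infected mice asks whether the sorted glia kept their profile. Genes of glial identity were far above their level in the rest of the layer, and neuron markers ranked higher in the glial sort by camera's preset correlation, though not with an estimated one (0.270). Macrophage genes, although they had risen in the glial sort, lay lower there than in non-glia. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 1072 of 14563 genes were higher in glia and 1074 lower, against 2574 and 1532 by DESeq2. Groups were apart for 4327 genes (29.7%), where chance gives 2.86%, and the count was 1179 without infected glia 1 and 1212 without infected glia 2. Of 20 enteric glia markers 19 were higher, with a median of 6.99 (camera adjusted p = 4.54e-21, 0.0562 with an estimated correlation). Sox10 stood at 300.0 ± 152 against 0.644 ± 0.321 CPM (n = 4 each; log2 8.85, adjusted p = 1.90e-05), and S100b (log2 7.06, adjusted p = 6.66e-05) and Gfap (8.17, 2.98e-04) were higher as well. The gap junction gene Gjc3 (9.33, 9.39e-05), the glial cadherin gene Cdh19 (9.18, 1.35e-05) and the phagocytic receptor gene Megf10 (8.96, 6.15e-05) were among the genes furthest above non-glia. Infected glia 5 raised the value for Gjc3, at 590.4 CPM against 156 in the next library. Chat, which makes the transmitter acetylcholine, was highest of the genes named in this comparison, at a log2 difference of 10.07 (0.0107), and its difference shrank to 4.34 without infected glia 5. Neuron markers had 4 of 17 higher (2.87, 4.57e-05, 0.270 with an estimated correlation).

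With an estimated correlation, macrophage markers (adjusted p = 0.0256) and cytokines and chemokines (0.0256) were lower in infected glia, and no other list passed in either direction. Macrophage markers were lower for 12 of 13 genes (median -3.43, 2.18e-11 with camera's preset correlation) and cytokines for 16 of 30 (-2.83, 3.19e-07). The macrophage growth factor receptor gene Csf1r was lower by a log2 difference of -3.74 (edgeR adjusted p = 1.46e-04) and Arg1 by -3.32 (0.00232). Type 2 genes (13 of 18 lower, list adjusted p = 2.61e-10), MHC class II (6 of 10, 4.55e-07), T and NK cell (3 of 16, 3.06e-07), monocyte (6 of 8, 1.15e-04) and neutrophil markers (5 of 7, 1.46e-05) lay lower with the preset correlation. So did B and plasma cell (2 of 4, 0.00202), eosinophil (2 of 5, 0.00558), erythroid (3 of 4, 5.32e-05), endothelial (3 of 12, 1.96e-04), mesothelial (2 of 8, 0.00301) and fibroblast markers (5 of 11, 0.00558). Epithelial markers were lower for 5 of 10 (5.66e-06), and the enterocyte genes Lypd8 (-9.89, 0.00232) and Akp3 (-7.92, 0.00138) were among the genes furthest below non-glia. Cell cycle genes (1 of 28 lower, 0.00188), MHC class I (1 higher and 2 lower of 20, 0.0329) and the type I (1 higher and 7 lower of 32, 0.0104) and interferon-gamma lists (2 higher and 4 lower of 35, 0.0395) ranked lower, and cholesterol synthesis (5 of 20 higher, 0.0324, but 0.443 with an estimated correlation) higher. The adjusted p of the interferon-gamma list was 0.0864 without infected glia 1, 0.0994 without infected glia 3, 0.0564 without infected non-glia 2 and 0.0901 without infected non-glia 4 and 0.0544 with the replicate block, and that of the type I list 0.0769 without infected non-glia 4. For MHC class I it was 0.0938 without infected glia 1, 0.0648 without infected glia 2 and 0.0973 without infected non-glia 4 and 0.0501 with a term for library class, and for cholesterol synthesis 0.0621 without infected glia 1, 0.121 without infected glia 5, 0.0956 without infected non-glia 2 and 0.0507 without infected non-glia 3 and 0.0880 among low-class libraries. Among low-class libraries the median was -0.56 for the interferon-gamma and -0.91 for the type I list. Among high-class ones, with infected glia 5 alone on the glial side, it was 0.09 and 0.07. Against the trend of the interferon-gamma list, Gbp10 was higher in glia, at 64.7 ± 20.9 against 7.49 ± 3.52 CPM (log2 3.16, adjusted p = 0.00165). Ifngr2 was lower in glia (log2 -1.74, adjusted p = 0.0330; 0.103 without infected glia 1, 0.0932 without infected glia 2, 0.0894 without infected glia 3, 0.0505 without infected non-glia 2, 0.0543 without infected non-glia 3 and 0.0580 without infected non-glia 4), while Ifngr1 (-0.55, 0.436) and Cxcl10 (0.12, 0.866) did not pass. Smooth muscle (0.122), interstitial cell of Cajal (0.151), neurotrophic (0.110), reactive glia (0.0922), matrix (0.405), interferon receptor (0.253), immediate early (0.704), mitochondrially encoded (0.565) and sex-linked lists (0.277) did not pass. Smooth muscle (0.0366 without infected glia 2 and 0.0445 without infected non-glia 1) and interstitial cell markers (0.0330 without infected non-glia 4) did with 1 library left out, and interferon receptors among low-class libraries (0.0379, median -0.87). Mast cell markers had fewer than 3 tested members.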

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

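The 8 tests of explanations for the interferon-gamma, leukocyte and sex-linked patterns were chosen after the results were seen, and the comparisons with other splits of the libraries before.

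Other splits of the same 8 libraries into 4 and 4 show how often a result as large comes without the real groups; there are 35, the real one included. For the 234 genes called on infection in non-glia 1 of 35 splits gave as many (highest other 1, and 1 among the 8 splits described below). Naive and infected non-glia of numbers 1, 2 and 4 deviated together (0.188, 0.172 and 0.193), and those of number 3 did not (-0.121). The splits alone therefore do not exclude chance for this count. A share of 1 in 35 is the smallest these splits can give, and several counts were each read on their own. For the 2146 between fractions in infected mice 1 of 35 gave as many (highest other 1, and 0 among the 8 splits described next). There pairs 1 and 2 deviated together (0.306 and 0.157) and pair 3 did not (-0.0816), so the splits alone cannot exclude chance for the 2146. The 20 enteric glia markers, a list fixed beforehand, had a median log2 difference of 6.99, and of 6.99 among low-class libraries. In a sort on tdTomato this argues against chance for those markers. Where same-number libraries deviate together, only the 8 splits that part as many pairs compare with the real one, too few for a share under 0.05; the rest put both libraries of at least 1 pair on the same side. This holds for infection in glia, with 172 genes (1 of 35 splits gave as many; highest other 0, and 0 among the 8), 16 lists by the preset correlation (4 of 35; highest other 17, and 15) and 9 by an estimated one (1 of 35; 0, and 0). It holds as well for fractions in naive mice, with 3235 genes (1 of 35; 0, and 0) and 19 lists (7 of 35; 21, and 19). For lists by the preset correlation 3 of 35 splits gave as many as the 21 between fractions in infected mice (highest other 22), so chance cannot be excluded there. In non-glia only the real split gave 22 (1 of 35), but another gave 20, so that count says little against chance. With an estimated correlation, 1 of 35 splits called as many lists as the 1 on infection in non-glia (highest other 0) and the 2 between fractions in infected mice (highest other 1). Counts this small and this close do not exclude chance. For the difference in response, 5 of 100 drawn splits of all 16 libraries gave at least the 1 gene called, and 1 of them gave 105. What that split separated was not tested. For lists, 54 of 100 gave at least the 11 called (highest other 23). Chance can be excluded for neither.

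The infection response of 1 gene and 11 lists differed between the fractions in a test of the difference itself. On the log2 scale, glia minus non-glia, it was -3.64 for Fabp5 (adjusted p = 0.00298; called in each of the 16 fits with 1 library left out, but not with the replicate number as a block, at 0.109). With the preset correlation the median difference was 3.12 for enteric neuron markers (adjusted p = 4.12e-07), 1.73 for interstitial cells of Cajal (0.00242), 1.69 for cell cycle (0.00363), 1.59 for macrophages (0.00242), 1.46 for fibroblasts and PDGFRA cells (0.00130) and 1.07 for extracellular matrix and wound repair (0.0107). These 6 kept their calls in all 16 fits with 1 library left out. It was 1.09 for smooth muscle (0.00734; 0.0632 without infected glia 2 and 0.0741 without infected non-glia 1), 1.08 for cytokines and chemokines (0.0440; 0.0832 without naive glia 3, 0.101 without naive glia 4, 0.0678 without infected glia 2, 0.0595 without infected glia 3, 0.0655 without naive non-glia 2, 0.200 without naive non-glia 4, 0.142 without infected non-glia 1 and 0.135 without infected non-glia 2) and 0.80 for reactive glia (0.0440; 0.0766 without naive glia 3, 0.0535 without infected glia 1, 0.0632 without infected glia 2, 0.0595 without infected glia 3, 0.0514 without naive non-glia 2, 0.0683 without naive non-glia 3, 0.0574 without naive non-glia 4, 0.0741 without infected non-glia 1 and 0.0975 without infected non-glia 2). It was negative for type I interferon-stimulated genes (-0.32, 0.0440; 0.106 without naive glia 4, 0.154 without infected glia 1, 0.0543 without naive non-glia 1, 0.128 without naive non-glia 2, 0.0679 without naive non-glia 3, 0.0510 without infected non-glia 1, 0.137 without infected non-glia 2 and 0.412 without infected non-glia 4; 0.101 with the replicate block and 0.0737 with a term for library class) and mitochondrially encoded genes (-0.77, 0.0481; 0.332 without naive glia 4, 0.348 without infected glia 1, 0.17 without infected glia 2, 0.232 without naive non-glia 1, 0.111 without naive non-glia 2, 0.117 without naive non-glia 3, 0.245 without infected non-glia 3 and 0.714 without infected non-glia 4; 0.665 with that term and 0.962 among low-class libraries). With an estimated correlation the lowest adjusted p of any list was 0.527. Over all genes tested the median difference was 0.32, so the list medians are not to be read against 0.

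Of 259 groups of 4 values tested, 38 had 1 library far from the other 3 by Dixon's test. For normally distributed values chance gives about 1 in 20, here 13.0. Library measures and CPM, 139 of the 259 groups, were tested without a log scale, and skewed values can pass more often. Of the 38, 33 lay in high-class libraries and 5 in low-class ones. Many of the genes were named for a large fold change, so they are not a random sample, and genes and lists are not independent of each other.

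Naive non-glia 4, the high-class library of its group, stood apart most often. Its share of counts was 14.9% on mt-Rnr1 (next 3.97%) and 55.1% on mitochondrial rRNA and CT010467.1 (next 32.5%). In CPM, with the next library in parentheses, it was high in the myeloid genes Clec4d at 178 (3.54), C5ar2 at 67.2 (8.61), Hcar2 at 108 (10.8), Fgr at 56.5 (8.92), Asgr2 at 50.04 (2.38), Pik3r6 at 37.3 (5.77) and Lpxn at 18.3 (4.38). H2-Ob stood at 31.2 (2.38), Hdc at 52.1 (12.4), Clstn1 at 150.3 (68.2) and Nrbp2 at 78.8 (30.4), while epithelial markers averaged 2.01 in log2 CPM (4.02).

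Infected non-glia 4 held Cd8b1 at 134 CPM (30.0 in the next library), Tigit at 120.0 (21.5), Gzmk at 37.2 (10.3) and Muc2 at 123 (16.7). Its mean log2 CPM was low for mesothelial markers at 2.13 (4.79), fibroblasts and PDGFRA cells at 4.88 (6.17) and reactive glia at 3.63 (4.72). Infected glia 5 held Chat at 403 CPM (2.24), Igsf11 at 701 (196), Gjc3 at 590.4 (156), Cmtm5 at 239 (71.0) and Tarm1 at 26.4 (5.56), with a low reactive glia mean of 5.23 (6.16). Naive glia 4 held Tmprss5 at 278 CPM (120.3) and Vmn1r181 at 16.03 (3.96), with a cell cycle mean of -0.54 (1.38). Infected glia 3 had 8.24% of its counts on the gene model Gm10800 (0.155% in the next library). Single values stood apart for Prap1 in infected non-glia 3 at 77.0 CPM (13.9) and, lower than the rest, Fabp5 in infected non-glia 1 at 228 (302). In mean log2 CPM they did for the interferon-gamma list in naive non-glia 2 at 4.92 (4.73), T and NK cell markers in naive glia 3 at -2.03 (-1.49) and sex-linked genes at -0.16 (3.19) in naive non-glia 1 and -0.20 (3.43) in infected non-glia 3.

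The interferon-gamma response list rose in the sorted glia of infected mice, and RNA of other cells may have carried part of that rise. The list's rise in glia, as a share of its level in infected non-glia, had a median of 0.421 (quartiles 0.296 and 0.806). That lay above the 0.198 of T and NK cells (0.134 and 0.271), 0.0806 of monocytes and 0.0675 of macrophages. This argues against leukocyte RNA, in the mix that infected non-glia held, as the whole cause. In infected glia 5 the margin over T and NK cells was small (0.504 against 0.472). Infected non-glia 4 raised the level behind the T and NK share, with a mean log2 CPM of 6.32 (next 5.37). Shares without that library were not computed, and carry-over of only some leukocytes was not tested. The rise shares of the type 2 (0.0751), MHC class II (0.101) and cytokine lists (0.105) lay within the range of the leukocyte lists, and those of the type I (0.210, quartiles 0.129 and 0.342) and MHC class I lists (0.386, 0.204 and 0.456) overlapped T and NK cells in their quartiles, so leukocyte RNA stays open for these, while library class is argued against for the interferon-gamma list by a median log2 fold change of 1.97 among low-class libraries and 2.12 in all. RNA of neurons, smooth muscle or fibroblasts cannot be told apart as a source, because their markers stood in infected glia at a median 4.74 (6 markers of at least 5 CPM in infected non-glia), 0.720 (12) and 0.437 (10) of their level in infected non-glia, although the neuron markers rose over naive glia by a share of 2.96 in infected glia 1 and by -0.788 to 0.00844 in the other 3 libraries; reads shared among guanylate-binding paralogs stay open as well for Gbp10 (share 8.43). A response of the glia themselves, which the design's infected group would bring, stays a hypothesis.

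Macrophage, monocyte and T and NK cell markers rose in the infected glial sort too, although sorting on tdTomato was meant to remove those cells; Chil3 averaged 56.0 CPM there and 645 in infected non-glia, and Gzmb 48.0 and 209. Library class is argued against, since the lowest of the 3 lists' median log2 fold changes was 2.22 among low-class libraries and 2.41 in all. A larger share of non-glial RNA of all kinds could be the cause and cannot be told apart. The difference in response had a median of 1.34 over leukocyte markers and 1.34 over stromal ones, against 0.32 over all genes. The quartiles of leukocyte and stromal lists overlapped. A constant share whose makeup changed with infection cannot be told apart either: macrophage markers had a difference in response with an adjusted p of 0.00242 by the preset correlation, but 0.0746 by the rotation test fry and 0.527 by an estimated correlation, the lowest of the leukocyte lists by each. Uptake of leukocyte RNA or expression by the glia was not tested.

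Sex-linked genes did not always follow the replicate numbers. Y-linked RNA (Ddx3y, Eif2s3y, Kdm5d and Uty together) stood at 53.0 to 163 CPM in 13 libraries and at 0 in naive glia 1, naive non-glia 1 and infected non-glia 3. Naive glia 3 held Y-linked RNA and Xist at 198 CPM, where the other libraries with Y-linked RNA held at most 4.91, which argues against RNA of male mice only. The Xist level was 14.9% of that in naive glia 1, so a mixture of animals is a candidate explanation. Infected non-glia 3 held Xist at 606 CPM and infected glia 3 at 0.415, which argues against 1 mouse as the source of both; no biological explanation was tested.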

How the results depend on the processing

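The settings with a term for library class, with the low-class libraries alone and with infected glia 3 left out as well were chosen after seeing the data. Counts are of genes called, in the order infection in glia (172), infection in non-glia (234), fractions in naive (3235) and in infected mice (2146) and difference in response (1).

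DESeq2 size factors gave 175, 224, 3213, 2183 and 1, and a stricter filter 174, 240, 3182, 2151 and 1. Every gene called by both the reported fit and any other setting had the same sign in both. Size factors moved the median log2 fold change over all genes by 0.10 between fractions in infected mice, and by less in the other comparisons. Without a filter the counts were 676, 1224, 4060, 2924 and 219, with more genes tested. The DESeq2 Wald test gave 627, 1136, 4905, 4106 and 148, and limma-voom 656, 7333, 7858, 8751 and 3008; the cause was not tested. A test against a log2 fold change of 1, which asks for a larger change, gave 84, 19, 1754, 1165 and 1. With all 16 libraries in the fit the first 4 counts were 353, 631, 2261 and 3848; the cause was not tested. A term for library class gave 285, 503, 4841, 2560 and 2, and the low-class libraries alone 312, 6222, 7067, 5647 and 659, from fewer libraries. Without infected glia 3 as well, infection in glia gave 345. The cause was not tested.

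With the replicate number as a block, for which the pairing of the infected mice failed its check, the counts were 244, 114, 3363, 2078 and 0. Fabp5 had an adjusted p of 0.109 for the difference in response with this block. Leaving out 1 library at a time gave 15 to 197, 6 to 406, 2309 to 5119, 1179 to 2437 and 1 to 6 genes. The lowest counts came without naive glia 2, naive non-glia 1, naive glia 3 and infected glia 1 for the first 4; for the difference in response 15 of the 16 fits gave 1. The highest came without infected glia 1 for infection in glia, without naive non-glia 4 for infection in non-glia, fractions in naive mice and the difference in response (6), and without infected non-glia 4 for fractions in infected mice.

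Size factors left 120 of 120 entries for named genes on the same side of the threshold for infection in glia, 136 of 138 in non-glia, 134 of 135 and 139 of 141 between fractions and 125 of 125 for the difference in response. A gene named by several parts of the rule counts once within a comparison. Over all fits with 1 library left out, 115 values for infection in glia lost the threshold, 217 in non-glia, 35 and 120 between fractions and 0 for the difference in response, while 2, 11, 7, 12 and 0 passed it anew. The block ended 4, 22, 2, 20 and 1 of these calls. For lists, an estimated correlation ended the calls of 7, 21, 19, 19 and 11 lists in the same order, while a prior count of 0.5 changed 1 call, for the difference in response. Leaving out 1 library ended 7, 11, 0, 12 and 35 list calls over all such fits and brought 3, 4, 2, 3 and 28. Some signs reversed, and the cause was not tested. Mitochondrially encoded genes ranked the other way on infection in glia among low-class libraries without infected glia 3 (adjusted p = 0.00344). For the difference in response, epithelial (0.0392) and mitochondrially encoded genes (0.962) did so among low-class libraries. Between fractions in infected mice limma-voom gave log2 differences of 0.57 for mt-Co1 and 0.93 for mt-Nd1.

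Depth, the spread between libraries and groups of 4 together limit what these data can show, and depth alone was not varied. Simulated data had the depth, group size and spread per gene of these libraries, but only 50 genes changed at each size. Genes there varied independently, without library classes or pairs, and each rate came from a single draw. No 2-fold change was called in any comparison. Of 16-fold changes 82% were called in glia and 20% in the difference in response. Where more genes differ, as between the fractions, the threshold is less strict and these rates do not carry over. Lists with fewer than 3 members above the count filter were not tested.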

Other observations

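No test in this part was chosen after the result was seen. Some genes that set the sorted glia furthest apart have known roles in glia and nerve and their differences are added here. In naive mice, Tmprss5, a membrane-bound serine protease gene, stood at 151 ± 85.7 CPM in glia against 0.331 ± 0.335 in non-glia (log2 difference 8.72, edgeR adjusted p = 5.81e-05). Cmtm5, a gene of myelinating glia, differed by 8.53 (adjusted p = 1.11e-04), Rxrg, a retinoid receptor gene, by 8.50 (6.31e-05), and Igsf21, a synaptic adhesion gene, by 8.74 (6.73e-05). In infected mice Foxd3, a transcription factor gene of the neural crest from which enteric glia descend, stood at 59.7 ± 15.9 CPM in glia and 0.0865 ± 0.104 in non-glia (9.11, 6.66e-05), and Igsf11, an adhesion gene, differed by 9.09 (5.50e-05). These 6 calls held with each library left out.

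Genes of absorptive epithelium lay far below non-glia in infected glia. The fatty acid binding protein genes Fabp1 and Fabp2 differed by -7.68 (adjusted p = 0.00838) and -6.21 (0.00776) and the immunoglobulin transporter gene Pigr by -6.75 (0.00755), with each call held when any library was left out. The muscle layer holds no epithelium of its own, and how these cells or their RNA came into the non-glial fraction was not tested.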
